A study of Mus musculus with 6 samples.

How the data were processed

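RNA was sequenced from 6 samples of mouse spleen CD4+ T cells, 3 wild type (WT) and 3 with a conditional knockout (CKO) of protein phosphatase 2A (PP2A). Per the labels, poly(A) RNA was made into libraries that keep the strand by dUTP and was read as pairs of 150 nt. The submitters' processing notes name fastp, HISAT2, StringTie and the genome GRCm38, with no version, role or order. The annotation, the strand setting, the treatment of reads with several matching places and the step that produced the counts were not given in the sources used here.

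The table holds, per the file headers, an estimated count and an FPKM value for each gene and sample. The estimated counts were deposited by the authors as whole numbers that were not scaled between samples, so rounding changed nothing. Among deposited counts from 1 to 20, 39.9% were multiples of 4, where an even spread gives 25%. One read pair of 150 nt ends therefore appeared to be worth about 4 counts, and the totals overstate the number of fragments. The FPKM values are relative to gene length and library depth, per the file headers, and the authors deposited 0.0001 where a gene had no estimate. The design had assumed plain counts, and the test chosen for counts was kept for the estimated counts. A repeat on counts divided by 4 was added after the data were seen. Columns were matched to samples by the sample descriptions. The table listed 55450 genes, and every gene identifier was in GENCODE release M21, with the same coordinates for 52543. Coordinates are those of the table, on GRCm38. Of these identifiers, 1084 share a symbol with another, and such genes are named with a remark in the text.

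Total estimated counts ranged from 55600949 to 76265332 per sample, at about 4 counts for each read pair. No 2 libraries were duplicates, since counts divided by 4 differed between every pair of libraries by far more than sampling noise in a chi-square comparison. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

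The choices in this paragraph were made before the data were examined. Genes were kept by edgeR's filterByExpr on group, which left 16092 tested and 39358 not tested. Libraries were scaled by TMM, with factors from 0.968 to 1.02. CKO was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, and "edgeR adjusted p" refers to it. Fold changes are CKO over WT on the log2 scale with their standard error (SE). Levels are edgeR's CPM, counts relative to library size after TMM scaling, given as mean ± SD over 3 samples. Of the 35 fixed gene lists, the 32 with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 32 lists. An estimated correlation was run beside it, and so was fry, which tests whether a list changed at all, where camera tests it against the other genes. Members were also adjusted over the list alone. The rule for named genes took the PP2A catalytic and scaffold genes, 6 genes of follicular helper T cells, the 10 largest changes in each direction and up to 4 members of each list with the smallest p. Largest changes had to pass the test, reach a mean of 5 CPM in the higher group, have non-overlapping groups and carry an official symbol that is not a numbered gene model or a pseudogene.

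Genes named outside this rule were chosen after their values were seen. They are Slamf6, Il2ra in its lists, Egr1, Egr3, Dusp6, Zfp36, Dapl1, Hspa1a, Pcna-ps2, Cd79a, Ccdc69, and the genes of the enrichment terms. The alternatives chosen in advance were DESeq2 size factors, upper quartile scaling or library size alone in edgeR, no filter, a filter of 5 CPM in 3 samples, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 samples, each library left out in turn, and a replicate block. Chosen after the data were seen were the counts divided by 4 and rounded up, libraries thinned to the smallest total, and an offset in edgeR that removes each library's trend with the GC content and length of the longest GENCODE M21 transcript. Enrichment of the deposited GO and KEGG terms was tested by the hypergeometric test in scipy 1.17.1, against tested genes with a term, for 1974 terms of 10 to 500 genes, adjusted over 3948 tests. The terms among genes lower in CKO are not reported here.

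The scripts were tested on simulated data before use. In a simulated CKO against WT comparison of 16092 genes, edgeR recovered 8 of 100 genes changed 1.5-fold and 43 of 100 changed 2-fold, with 4 false among 55 calls. DESeq2 recovered 39 and 56 with 40 false among 135 calls, and limma-voom recovered 9 and 41 with 4 false among 54 calls. Camera called a raised interferon list and 0 of the 31 other lists. Genes were simulated independently of each other, so this does not test false calls of lists whose members change together. In the data the estimated correlation reached 0.40, in the mitochondrially encoded genes. With a simulated GC trend, the offset reduced the false calls from 20 to 4, and the changed genes recovered fell from 61 to 54 of 200.

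Genes whose coordinates overlap another tested gene can share reads where the counting ignored strand, which was not given in the sources used here. Of 540 named or listed genes, 65 overlapped a gene at 10% or more of their own level. Near-identical copies such as the globin, Hspa1 and Ifit3 genes and pseudogenes have uncertain counts for the same reason. Exon-level reads over the deleted part of the PP2A gene were not analysed here.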

Results

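CD4+ T cells from the spleen of mice were profiled after stimulation through the T cell receptor. Naive cells had been held for 1 hour on plates coated with 2 µg/ml of antibodies to CD3 and CD28, which stand in for antigen and costimulation. The WT group had 3 samples and the CKO group had 3 samples. PP2A is a serine/threonine phosphatase assembled from a catalytic, a scaffold and a regulatory subunit, and the series title links it to follicular helper T (Tfh) cells, which help B cells, in lupus. Total estimated counts were 72704574, 72322516 and 76265332 in WT replicates 1 to 3, and 55600949, 74085775 and 61181029 in CKO replicates 1 to 3. Mitochondrially encoded genes took 4.61% to 5.80% of the counts.

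The first question was which PP2A gene differed between the genotypes. Ppp2ca, the gene of the catalytic alpha subunit (ENSMUSG00000020349, chromosome 11, 52098681 to 52127778, GRCm38), fell in CKO. It measured 489, 477 and 479 CPM in WT replicates 1 to 3, and 339, 349 and 337 CPM in CKO replicates 1 to 3. The means were 482 ± 6.02 in WT and 342 ± 6.20 in CKO (SD, n = 3 each), a log2 fold change of -0.49 ± 0.04 (SE, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00263). The other catalytic gene, Ppp2cb, was at 98.0 ± 4.82 CPM in WT and 91.8 ± 3.23 in CKO and did not pass (edgeR adjusted p = 0.413). The scaffold genes Ppp2r1a and Ppp2r1b had log2 fold changes of -0.09 ± 0.05 and -0.11 ± 0.24 and did not pass either (edgeR adjusted p = 0.344 and 0.854). Among 18 measured PP2A subunit genes, 1 rose and 1 fell over all genes, with the same counts adjusted over the list alone. The gene that rose was Ppp2r5d, a regulatory subunit, by 0.34 ± 0.07 (edgeR adjusted p = 0.0383). The list did not move as a set (camera adjusted p = 0.415). The labels do not name the deleted subunit, and reads from exons outside a deletion remain in a gene count, so the level in CKO does not measure the share of cells with the deletion. The call of Ppp2r5d was lost when any 1 of the 6 libraries was left out (edgeR adjusted p from 0.0558 to 0.123). It was also lost with no filter on low counts (0.0538) and after correction for GC content and length (0.0801). Its coordinates overlap Mea1 on the opposite strand, a gene at 59.0% of its level.

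**Figure D1:**
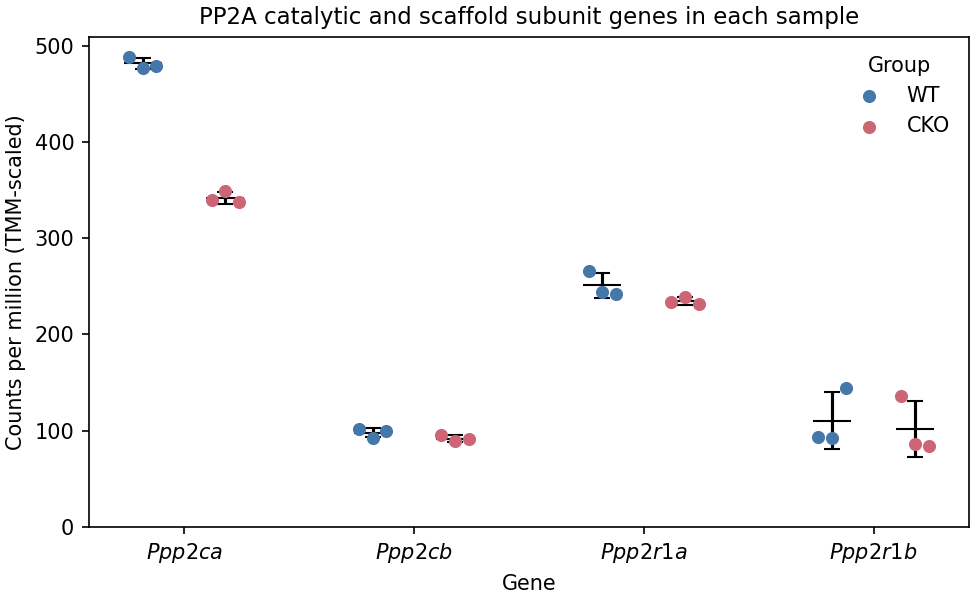
CPM, scaled by TMM, of 4 PP2A subunit genes in each WT and CKO sample (points), with the mean (horizontal line) and SD (bars) of 3 samples. Ppp2ca lies between 337 and 349 in CKO and between 477 and 489 in WT, while the groups of Ppp2cb and Ppp2r1b overlap.

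Across the transcriptome, 809 of 16092 tested genes changed in CKO, 304 higher and 505 lower. The first principal component, with 23.9% of the variance, placed the WT samples from -47.4 to -23.0 and the CKO samples from 25.5 to 37.8. The second, with 21.5%, did not separate the groups and spread the CKO samples from -46.7 to 54.9 and the WT samples from -14.2 to 9.37. Most changes were small, and 48 genes changed at least 2-fold, 29 higher and 19 lower. Among genes that met the rule for largest changes, which leaves out pseudogenes and numbered models, the first to rise was Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), from 5.71 ± 0.756 to 54.4 ± 0.982 CPM. Its log2 fold change was 3.25 ± 0.11 (edgeR adjusted p = 1.7e-04). Ctdsp2, a phosphatase gene (chromosome 10, 126978717 to 126999975), fell from 324 ± 13.3 to 97.2 ± 7.56 CPM, by 1.74 ± 0.07 on the log2 scale (edgeR adjusted p = 2.2e-04). The interferon-inducible gene Oasl2 (chromosome 5, 114896936 to 114912234) fell from 16.7 ± 0.561 to 4.98 ± 0.204 CPM (edgeR adjusted p = 7.7e-04). The other genes with the largest rises under this rule were the hemoglobin genes Hbb-bs, Hbb-bt and Hba-a1 with log2 fold changes of 1.98, 1.95 and 1.82. Drc1 rose by 1.65, the interferon-inducible Ifit3b and Mx1 by 1.63 and 1.32, the heat shock gene Hspa1b by 1.44, Ly6c2 by 1.41 and Ccrl2 by 1.33. The other genes with the largest falls under this rule were Sssca1 with -1.98, Amn1 with -1.19, the cyclin gene Ccnc with -0.93 and Emp1 with -0.88. They were followed by the nuclear receptor gene Nr4a2 with -0.77, Taf13 with -0.75, the RNA-binding regulator gene Zc3h12d with -0.69 and the ubiquitin ligase gene Mib1 with -0.67. Groups that do not overlap were a condition for these 20 genes. Of all tested genes, 27.6% had such groups, against 10% by chance.

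The split of 304 higher to 505 lower differed with the processing. It was 297 to 535 with DESeq2 size factors, 306 to 483 with upper quartile scaling and 345 to 360 with library size alone. On log2(FPKM + 1) and log2(FPKM + 0.1), where the test and the filter also differed, it was 466 to 406 and 451 to 403. After correction for GC content and length it was 210 to 199, with 409 genes passing. Genes called lower had a median GC content of 43.9% and a median length of 4545 nt, those called higher 52.8% and 3059 nt, and those not called 49.3% and 3278 nt. These medians cover only genes with a mean log2 CPM above 2, which were 493 lower, 290 higher and 8762 not called. The count of 809 fell to 301, 224 and 223 without WT replicate 1, 2 or 3, and to 210, 149 and 362 without CKO replicate 1, 2 or 3. Of the 20 genes with the largest changes, Slc15a2, Hbb-bs, Hbb-bt, Hba-a1, Ifit3b, Mx1, Sssca1, Oasl2, Ctdsp2 and Zc3h12d passed without each library in turn. Without CKO replicate 2, the edgeR adjusted p was 0.0536 for Drc1, 0.0517 for Hspa1b, 0.0556 for Taf13, 0.0608 for Ccrl2, 0.0569 for Amn1, 0.137 for Ccnc, 0.102 for Emp1 and 0.131 for Nr4a2. These were the highest of the 6 for each gene. Amn1 was also lost without WT replicate 3, and Ccrl2 without WT replicate 2 or CKO replicate 1. Nr4a2 was lost without any library but CKO replicate 3, Ccnc without any but WT replicate 1, and Emp1 without any of the 6. Ly6c2 was lost without WT replicate 1, WT replicate 2 or CKO replicate 1 (edgeR adjusted p of up to 0.0575), and Mib1 without any library but CKO replicate 1 (up to 0.107). The correction for GC content and length ended the calls of Ccnc (edgeR adjusted p = 0.085), Nr4a2 (0.0515) and Mib1 (0.073). Of the other settings, Ccnc was lost in 5 (edgeR or limma adjusted p from 0.0528 to 0.0739) and Emp1 on log2(FPKM + 1) and log2(FPKM + 0.1) (limma adjusted p = 0.0572 and 0.0603). The Sssca1 gene measured here (ENSMUSG00000118125) shares its symbol and overlaps Fam89b on the same strand, which had a log2 fold change of 1.63 and did not pass (edgeR adjusted p = 0.0942), so its level is uncertain.

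Genes of the Tfh program moved in both directions. Among 24 measured members, 3 rose, 2 fell and 19 did not pass, and adjusted over the list alone 7 rose and 3 fell. P2rx7, an ATP-gated channel gene that restrains Tfh cells, rose from 6.35 to 12.2 CPM, a log2 fold change of 0.94 ± 0.13 (edgeR adjusted p = 0.0146), and the transcription factor gene Batf rose by 0.42 ± 0.07 (0.0231). The receptor gene Slamf6 rose by 0.27 ± 0.05 (0.0291). Icos, the costimulatory receptor gene needed for Tfh cells, fell from 358 ± 6.86 to 302 ± 7.16 CPM, with a log2 fold change of -0.24 ± 0.04 (edgeR adjusted p = 0.0193). The inhibitory receptor gene Btla fell by 0.30 ± 0.05 on the log2 scale (0.0207). Bcl6, the transcription factor gene that defines the lineage, was at 111 ± 4.76 CPM in WT and 103 ± 2.12 in CKO, a log2 fold change of -0.11 ± 0.05 that did not pass (edgeR adjusted p = 0.285). Cxcr5, Pdcd1, Il21 and Tcf7 had log2 fold changes of 0.10, 0.08, -0.22 and 0.10 and did not pass (edgeR adjusted p = 0.707, 0.765, 0.219 and 0.143). The list did not move as a set, with a median of 0.08 and a camera adjusted p of 0.663. The calls of Icos, Btla, Batf and Slamf6 were lost without any 1 of the 6 libraries (edgeR adjusted p of up to 0.0761, 0.0744, 0.0845 and 0.107). Those of Icos, Btla and Batf were also lost after correction for GC content and length (0.0908, 0.102 and 0.0585). That of P2rx7 was lost without WT replicate 1, CKO replicate 1 or CKO replicate 2, with an edgeR adjusted p of up to 0.0628.

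Among genes that oppose the Tfh fate, the members that changed all fell. Of 12 measured members, 0 rose, 5 fell and 7 did not pass, and the counts were the same adjusted over the list alone. Il7r, the interleukin 7 receptor gene of resting T cells, fell from 754 to 548 CPM, by 0.46 ± 0.03 on the log2 scale (edgeR adjusted p = 0.00263). Stat5b, which carries interleukin 2 signals, fell by 0.32 ± 0.04 (edgeR adjusted p = 0.0127), and the lymphocyte egress receptor gene S1pr1 by 0.21 ± 0.04 (0.0292). The selectin ligand gene Selplg fell by 0.26 ± 0.05 (0.0344) and the interleukin 2 receptor gene Il2ra by 0.53 ± 0.11 (0.0463). The list passed camera (adjusted p = 0.0133, median -0.05, mean -0.13) and did not pass with an estimated correlation (adjusted p = 0.389 with an estimated correlation). It also did not pass on log2(FPKM + 1) (adjusted p = 0.0862) or with a filter of 5 CPM (0.0808). Il7r passed without each library in turn, when 1 or 2 members fell. Stat5b was lost without WT replicate 2, CKO replicate 1 or CKO replicate 2, Selplg without every library except WT replicate 2, and S1pr1 and Il2ra without any 1 of the 6, with edgeR adjusted p of up to 0.068, 0.12, 0.115 and 0.133. After correction for GC content and length the edgeR adjusted p was 0.0665 for S1pr1 and 0.0919 for Il2ra.

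The immediate early genes that changed, switched on within minutes of receptor engagement, mostly rose, while Egr1, Egr3 and Nr4a2 fell. Of 29 measured members, 11 rose, those 3 fell and 15 did not pass, and adjusted over the list alone 16 rose and 8 fell. Fos rose from 435 to 671 CPM, a log2 fold change of 0.63 ± 0.04 (edgeR adjusted p = 0.00141), and Jun rose from 173 to 251 CPM, by 0.54 ± 0.05 (0.00546). The phosphatase genes Dusp1 and Dusp2, whose products switch off MAP kinases, rose by 0.54 ± 0.04 and 0.54 ± 0.06 (edgeR adjusted p = 0.00263 and 0.00743). Among the 7 further members that rose were Dusp6, by 0.58, and the RNA-binding protein gene Zfp36, by 0.46 (edgeR adjusted p = 0.00842 and 0.00743). The 3 that fell were the transcription factor genes Egr1, from 845 to 639 CPM with a log2 fold change of -0.40 ± 0.07 (edgeR adjusted p = 0.025), Egr3 with -0.37 ± 0.07 (0.0332) and Nr4a2 with -0.77 ± 0.15 (0.0369). As a set, the immediate early genes passed camera upward (adjusted p = 2.5e-04, median 0.22) and did not pass with an estimated correlation (adjusted p = 0.389 with an estimated correlation). The mean over the list, centred per gene, was 0.05 in WT replicate 1 and 0.03 in CKO replicate 2, so the groups overlapped. Fos, Jun, Dusp1, Dusp2, Dusp6 and Zfp36 passed without each library in turn. The number of members that rose ranged from 6 without WT replicate 2 to 12 without WT replicate 1, and was 7 without WT replicate 3, CKO replicate 1 or CKO replicate 2. Egr1 and Egr3 passed only without WT replicate 3, with edgeR adjusted p of up to 0.0876 and 0.112 without the others. Nr4a2 passed only without CKO replicate 3 (edgeR adjusted p = 0.0275, up to 0.131 without the others, 0.0515 after correction for GC content and length).

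The targets of NF-kB that changed all rose. Of 21 measured members, 4 rose, 0 fell and 17 did not pass, and 6 rose adjusted over the list alone. Nfkbia, the inhibitor that NF-kB itself induces, rose from 336 to 463 CPM, a log2 fold change of 0.46 ± 0.04 (edgeR adjusted p = 0.00328). The adhesion molecule gene Icam1 rose by 0.74 ± 0.07, to 36.8 CPM (0.00498). Gadd45b and Nfkbie rose by 0.47 ± 0.07 and 0.54 ± 0.09 (edgeR adjusted p = 0.0177 and 0.0253). These targets passed camera (adjusted p = 8.3e-04, median 0.14) but not with an estimated correlation (adjusted p = 0.305 with an estimated correlation). The mean over the list, centred per gene, did not separate the groups, at -0.03 in CKO replicate 1 and -0.02 in WT replicate 1. Nfkbia and Icam1 passed without each library in turn. Gadd45b reached 0.0679 without WT replicate 3 and was also lost without WT replicate 1, WT replicate 2 or CKO replicate 2. Nfkbie reached 0.0998 without CKO replicate 2 and was also lost without WT replicate 1, WT replicate 3 or CKO replicate 1 and after correction for GC content and length (0.0515).

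Surface genes of activation and components of T cell receptor signalling moved both ways. Of 18 activation surface genes, 4 rose, 3 fell and 11 did not pass, and adjusted over the list alone 7 rose and 5 fell. The transferrin receptor gene Tfrc rose by 0.43 ± 0.06 and the early activation marker gene Cd69 by 0.29 ± 0.04, from 983 to 1199 CPM (edgeR adjusted p = 0.011 and 0.0139). Cd5, the gene of a receptor that restrains T cell receptor signals, rose by 0.23 ± 0.04 (edgeR adjusted p = 0.0183), and Icos fell. Of 28 signalling components, 3 rose, 3 fell and 22 did not pass, and adjusted over the list alone 7 rose and 3 fell. Cblb, a ubiquitin ligase gene that limits T cell activation, fell from 641 to 426 CPM, by 0.59 ± 0.06 on the log2 scale (edgeR adjusted p = 0.00743). The phosphatase gene Ptpn22 fell by 0.38 ± 0.06 (0.0195). The CD3 chain gene Cd3g and the exchange factor gene Vav1 rose by 0.29 ± 0.04 and 0.32 ± 0.05 (edgeR adjusted p = 0.0127 and 0.0152). Neither list passed camera (adjusted p = 0.378 for surface genes and 0.0719 for signalling components). The second had an adjusted p of 0.0415 on log2(FPKM + 1) and of 0.0158 without WT replicate 1. Cblb passed without each library in turn. Ptpn22 passed only without CKO replicate 3 (edgeR adjusted p = 0.0134, up to 0.085 without the others). Without CKO replicate 2 the edgeR adjusted p was 0.0504 for Tfrc, 0.0717 for Cd69, 0.086 for Cd5, 0.0659 for Cd3g and 0.0722 for Vav1, in each case the highest of the 6. Cd69 was also lost without WT replicate 2 or 3, Cd3g and Vav1 without WT replicate 2 or CKO replicate 1, and Vav1 without WT replicate 1. Cd5 was lost without any of the 6 and after correction for GC content and length (0.0861).

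Interferon stimulated genes formed the group with the most changed members. Of 28 measured, 18 rose, 1 fell and 9 did not pass, and adjusted over the list alone 24 rose and 1 fell. Xaf1 rose from 23.5 ± 1.65 to 50.8 ± 2.55 CPM, a log2 fold change of 1.11 ± 0.08 (edgeR adjusted p = 0.00263). Irf7, the transcription factor gene that amplifies type I interferon production, rose from 37.7 ± 2.78 to 71.0 ± 4.24 CPM, by 0.91 ± 0.08 (edgeR adjusted p = 0.00376). Oas2, a sensor of double-stranded RNA, rose from 15.7 ± 2.46 to 38.7 ± 1.42 CPM, by 1.30 ± 0.12 (edgeR adjusted p = 0.00484). The 1 member that fell was Oasl2, by 1.74 ± 0.09 on the log2 scale, against the direction of every other measured member. The median of the list was 0.54, and it passed camera (adjusted p = 9.3e-18). It was the only 1 of the 32 lists to pass with an estimated correlation (adjusted p = 0.0172 with an estimated correlation). Xaf1, Irf7, Oas2 and Oasl2 passed without each library in turn. The number of members that rose was 13, 10 and 11 without WT replicate 1, 2 or 3 and 9, 8 and 12 without CKO replicate 1, 2 or 3. Irf7 overlaps Phrf1 on the opposite strand, a gene at 125% of its level with a log2 fold change of -0.01. Ifit3 and Ifit3b are near-identical copies with uncertain counts. The hemoglobin genes Hbb-bs and Hbb-bt were also higher in the same 3 CKO libraries, by 1.98 and 1.95 on the log2 scale.

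**Figure D2:**
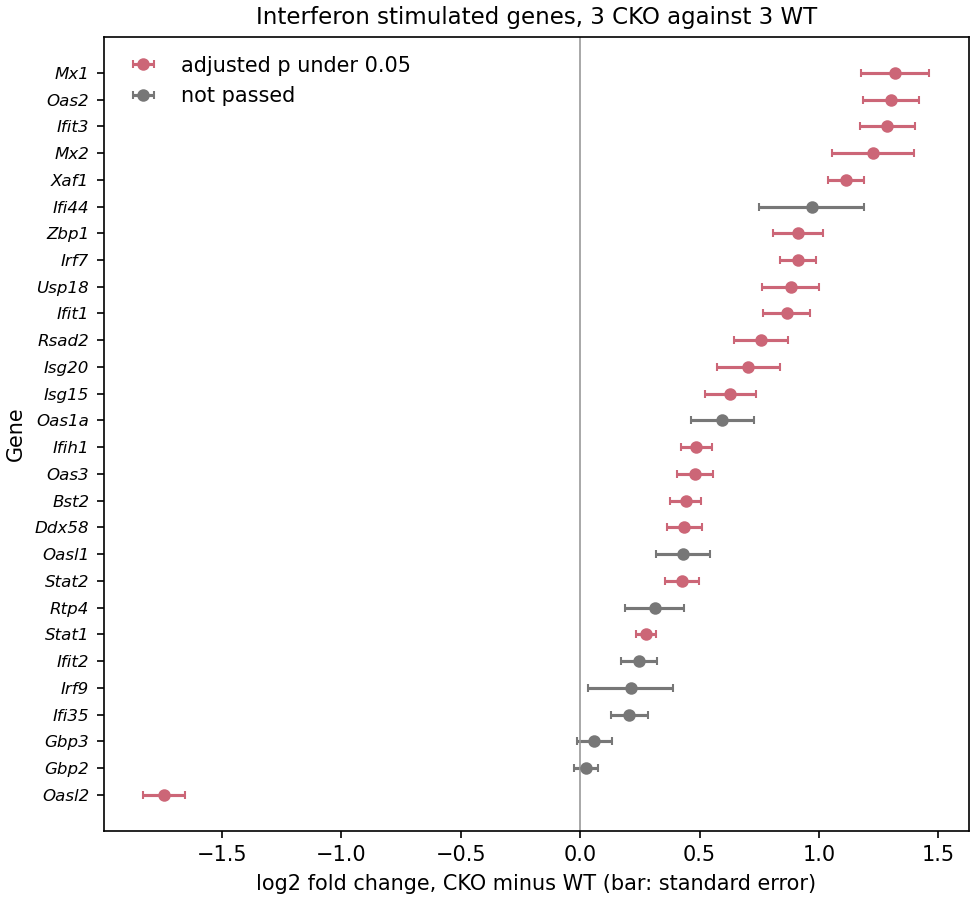
The log2 fold change, CKO minus WT, of the 28 measured interferon stimulated genes (points) with the standard error (bars), from 3 CKO and 3 WT samples. The 18 members that rose and Oasl2, the 1 that fell, are coloured, and the 9 that did not pass are grey.

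The heat shock genes that changed also rose. Of 13 measured, 5 rose, 0 fell and 8 did not pass, and 7 rose adjusted over the list alone. Hspa5, a chaperone gene of the endoplasmic reticulum, rose from 1345 to 1679 CPM, a log2 fold change of 0.32 ± 0.03 (edgeR adjusted p = 0.00531). Hsph1 rose by 0.54 ± 0.06 (0.00853), and Hsp90ab1 rose by 0.24 ± 0.03 (0.0141). The near-identical copies Hspa1a and Hspa1b rose by 1.17 and 1.44, at 6.47 and 16.7 CPM in CKO (edgeR adjusted p = 0.0342 and 0.0102). The heat shock list passed camera (adjusted p = 6.2e-07, median 0.24) but not with an estimated correlation (adjusted p = 0.137 with an estimated correlation). It had 2 members that rose without CKO replicate 2 and 3 without WT replicate 2, WT replicate 3 or CKO replicate 1. Hspa5 and Hsph1 passed without each library in turn, and Hsp90ab1 was lost without WT replicate 2, WT replicate 3, CKO replicate 1 or CKO replicate 2, with an edgeR adjusted p of up to 0.073. Hspa1b was lost without CKO replicate 2 (0.0517) and Hspa1a without any library but CKO replicate 3 (up to 0.113) and after correction for GC content and length (0.0665).

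Few glycolysis and cell cycle genes changed, and those that did rose. Of 18 glycolysis genes, 2 rose, 0 fell and 16 did not pass, and 3 rose adjusted over the list alone. The enzyme genes Aldoa (ENSMUSG00000030695, a shared symbol) and Pfkl rose by 0.34 ± 0.06 and 0.24 ± 0.05 (edgeR adjusted p = 0.0233 and 0.043). Both calls ended after correction for GC content and length (edgeR adjusted p = 0.0735 and 0.146). Glycolysis genes passed camera (adjusted p = 7.8e-04, median 0.18) but not with an estimated correlation (adjusted p = 0.393 with an estimated correlation) or in fry, which tests the list alone and not against other genes (adjusted p = 0.0669). Of 26 cell cycle genes, 2 rose, 0 fell and 24 did not pass, and 4 rose adjusted over the list alone. Mki67, a marker of proliferating cells, rose from 7.52 to 12.6 CPM, by 0.74 ± 0.12 (edgeR adjusted p = 0.0223). Pcna rose by 0.28 ± 0.04 (0.0111), while its near-identical pseudogene Pcna-ps2 fell from 15.7 to 2.99 CPM, with a log2 fold change of -2.39 ± 0.11 (edgeR adjusted p = 4.2e-04). Whether the 2 shared reads was not tested, so the level of Pcna is uncertain. Cell cycle genes passed camera (adjusted p = 0.00204, median 0.25) but not with an estimated correlation (adjusted p = 0.294 with an estimated correlation). Without CKO replicate 2 the edgeR adjusted p was 0.0944 for Aldoa, 0.0634 for Pcna and 0.084 for Mki67, the highest of the 6. Aldoa and Pcna were also lost without WT replicate 2, WT replicate 3 or CKO replicate 1, and Mki67 without these or CKO replicate 3. Pfkl was lost without any 1 of the 6 libraries (edgeR adjusted p from 0.0932 to 0.147), and Mki67 on log2(FPKM + 0.1) (limma adjusted p = 0.0543).

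Few genes of the T helper subsets changed. Of 8 measured Th2 genes, 2 rose, 0 fell and 6 did not pass, with the same counts adjusted over the list alone. The lineage factor gene Gata3 rose from 36.9 to 50.4 CPM, by 0.45 ± 0.08, and Nfil3 rose by 0.31 ± 0.07 (edgeR adjusted p = 0.0317 and 0.0473). Both calls were lost without any 1 of the 6 libraries (edgeR adjusted p of up to 0.109 and 0.142) and after correction for GC content and length (0.0515 and 0.114). The Th2 list passed camera (adjusted p = 0.0152, median 0.23) but not with an estimated correlation (adjusted p = 0.305 with an estimated correlation), nor with camera without CKO replicate 1 (adjusted p = 0.0512) or after that correction (0.0842). Of 4 measured Th17 genes, 1 fell, 0 rose and 3 did not pass, and 2 fell adjusted over the list alone. The 1 that fell was Stat3, a signal transducer gene shared by many cytokines, by 0.20 ± 0.03 (edgeR adjusted p = 0.0226). Stat3 overlaps Stat5a and was lost without any 1 of the 6 libraries (edgeR adjusted p of up to 0.0965). The Th17 list passed camera downward (adjusted p = 0.00842, median -0.24) but not with an estimated correlation (adjusted p = 0.294 with an estimated correlation). Of 12 Th1 genes, the interferon gamma receptor gene Ifngr1, Il18r1 and Stat4 fell by 0.31, 0.54 and 0.23, Runx3 rose by 0.35 and 8 did not pass. Adjusted over the list alone 4 fell and 1 rose, and the list did not pass camera (adjusted p = 0.0719, but 0.0288 without WT replicate 2 and 0.0487 after the correction). Ifngr1 was lost without CKO replicate 2 (edgeR adjusted p = 0.0543), Runx3 without any library but CKO replicate 3 (up to 0.114), and Il18r1 and Stat4 without any of the 6 (up to 0.0788 and 0.116). The correction also ended the calls of Stat4 and Runx3 (0.0737 and 0.0928). Of 14 Treg genes, Ctla4 and Il2ra fell by 0.31 and 0.53, 0 rose and 12 did not pass, with 2 in each direction adjusted over the list alone (camera adjusted p = 0.449). Ctla4 passed only without WT replicate 1, and Il2ra was lost without any of the 6 (edgeR adjusted p of up to 0.141 and 0.133), and the correction ended both calls (0.112 and 0.0919).

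**Figure D3:**
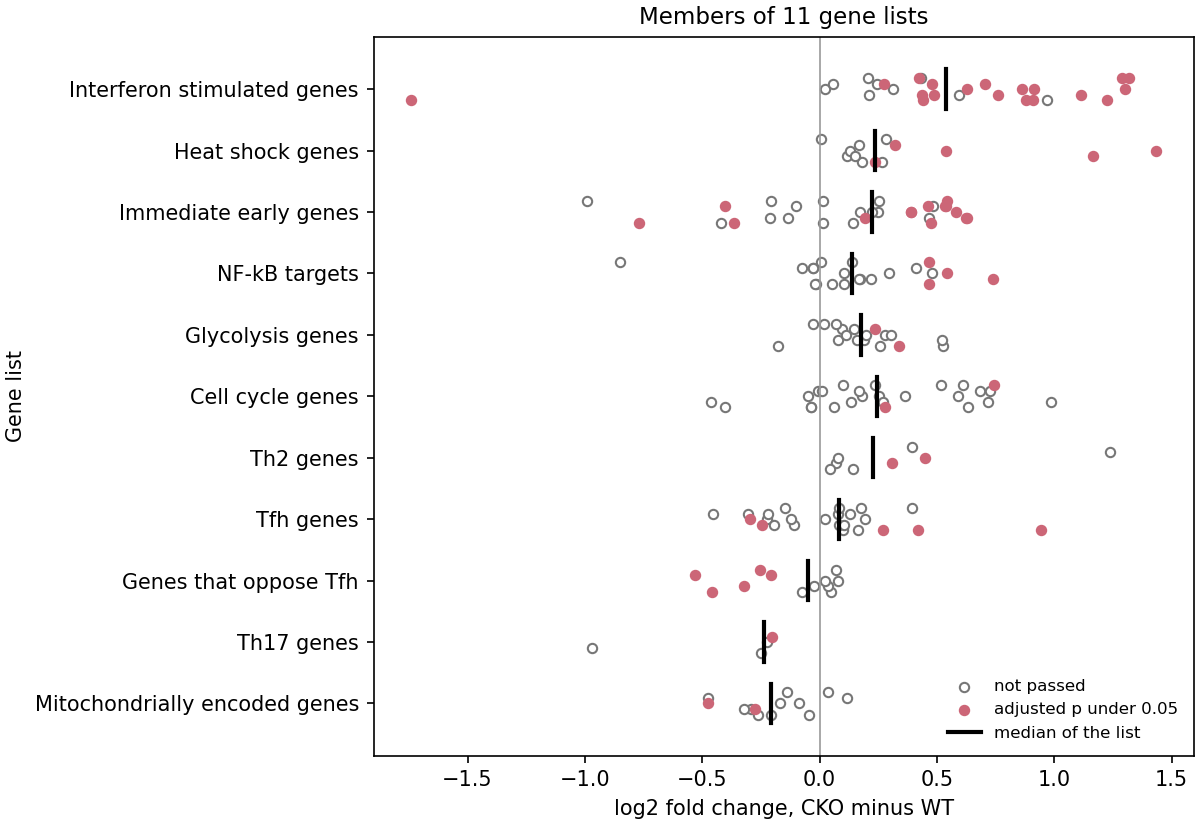
The log2 fold change, CKO minus WT, of each measured member of 11 gene lists (points) with the median of each list (vertical line). Filled points passed at an adjusted p under 0.05, and the interferon stimulated genes have the largest median of the lists drawn, 0.54. Erythroid and platelet markers, with a median of 1.88, also passed camera and are not drawn, while the Tfh list, which is drawn, did not pass.

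Genes of resting T cells, cytokines and memory cells gave single changes. Of 23 naive and quiescence genes, 1 rose, 4 fell and 18 did not pass, and adjusted over the list alone 4 rose and 7 fell. Klf3, Satb1, Il7r and S1pr1 fell, the first by 0.40 ± 0.04 (edgeR adjusted p = 0.0058) and the second by 0.28 ± 0.05 (0.0265), and Dapl1 rose by 0.50. The list had a median of 0.02 and a mean of 0.01, while camera pointed down and did not pass (adjusted p = 0.415). Satb1 was lost after correction for GC content and length (edgeR adjusted p = 0.106) and without WT replicate 2, WT replicate 3, CKO replicate 1 or CKO replicate 2 (up to 0.104). Dapl1 was lost without any library but CKO replicate 3 (up to 0.109), and S1pr1 without any of the 6 (up to 0.115) and after the correction (0.0665). Of 20 measured cytokines and chemokines, only Lif rose, from 84.5 to 146 CPM, by 0.79 ± 0.06 (edgeR adjusted p = 0.00263), while 0 fell and 19 did not pass. The counts were the same adjusted over the list alone (camera adjusted p = 0.162, but 0.0485 without WT replicate 1). Of 23 memory and effector genes, Ly6c2 and Itgb7 rose, the second by 0.31, 0 fell and 21 did not pass, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.442). Ly6c2 was lost without WT replicate 1, WT replicate 2 or CKO replicate 1 (edgeR adjusted p of up to 0.0575), and Itgb7 without any library but CKO replicate 3 (up to 0.117) and after the correction (0.15).

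Regulators of growth gave changes in both directions. Of 23 PI3K, Akt and mTOR components, 4 rose, 2 fell and 17 did not pass, and 4 rose and 4 fell adjusted over the list alone. Ddit4, an inhibitor of mTOR complex 1, rose from 19.9 to 36.9 CPM, by 0.89 ± 0.07 (edgeR adjusted p = 0.00263). The kinase gene Mtor rose by 0.33 ± 0.05 (0.0193), Sesn2, an inhibitor of the pathway, rose by 0.50 ± 0.08 (0.0207), and Sesn3, its relative, fell by 0.17 ± 0.03 (0.0383). That list had a median of -0.02 and a mean of 0.07, and it did not pass camera (adjusted p = 0.804). Ddit4 passed without each library in turn, while Mtor, Sesn2 and Sesn3 were lost without any 1 of the 6 (edgeR adjusted p of up to 0.0858, 0.0746 and 0.129) and Sesn3 after correction for GC content and length (0.248).

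Several other programs held few or no changed members. Of 19 Wnt and beta-catenin genes, only the corepressor gene Tle4 fell, by 0.34 ± 0.05 (edgeR adjusted p = 0.0127), and 18 did not pass. Adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.522). Tle4 was lost without WT replicate 2, WT replicate 3, CKO replicate 1 or CKO replicate 2 (edgeR adjusted p of up to 0.0651). Of 16 p53 targets, Gadd45a, Plk2 and Sesn2 rose by 0.79, 0.64 and 0.50, 0 fell and 13 did not pass. Adjusted over the list alone 5 rose (camera adjusted p = 0.0848, but 0.0283 after correction for GC content and length). In fry the p53 list passed upward (adjusted p = 0.00454). Gadd45a passed without each library in turn, Plk2 was lost without CKO replicate 2 (edgeR adjusted p = 0.0508), and Sesn2 without any of the 6 (up to 0.0746). Of 21 apoptosis regulators, the cell death gene Bmf rose by 0.74, the caspase inhibitor gene Xiap fell by 0.29 and 19 did not pass. The same counts held adjusted over the list alone (camera adjusted p = 0.469). Of 17 ATF4 targets, only Ddit3 (ENSMUSG00000025408, a shared symbol that overlaps Mars) rose, by 0.33, and 16 did not pass. Adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.0848, but 0.0283 without WT replicate 1). The ATF4 list also passed upward in fry (adjusted p = 0.0228). Of 19 cholesterol synthesis genes, Insig1 rose by 0.18 and 18 did not pass, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.771). Bmf, Xiap, Ddit3 and Insig1 were lost without any 1 of the 6 libraries (edgeR adjusted p of up to 0.118, 0.126, 0.112 and 0.159), and Bmf, Xiap and Insig1 after correction for GC content and length (0.0582, 0.366 and 0.0593). In edgeR, 0 of 24 ribosome biogenesis genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.0719, but 0.0463 without WT replicate 1). Of them, 1 was higher and 6 lower at an unadjusted p under 0.05, and 1 higher and 7 lower passed in DESeq2 and 0 in limma-voom. Of 30 oxidative phosphorylation genes, 0 passed in edgeR by either adjustment (camera adjusted p = 0.546). Of these, 1 was higher at an unadjusted p under 0.05, and 1 higher passed in DESeq2 and 0 in limma-voom. Of 13 mitochondrially encoded genes, mt-Nd6 and mt-Nd1 fell by 0.48 ± 0.05 and 0.27 ± 0.05 (edgeR adjusted p = 0.00743 and 0.0348) and 11 did not pass, with 3 falling adjusted over the list alone. That list passed camera (adjusted p = 0.00506, median -0.21) but not with an estimated correlation (adjusted p = 0.408 with an estimated correlation), in fry (adjusted p = 0.174), without WT replicate 3 (camera adjusted p = 0.0804) or after correction for GC content and length (0.229). The mean over that list, centred per gene, was -0.17 in WT replicate 2 and -0.03 in CKO replicate 1, so the groups overlapped. The call of mt-Nd1 was lost without any 1 of the 6 libraries (edgeR adjusted p of up to 0.104) and after that correction (0.179), and mt-Nd6 overlaps mt-Nd5 on the opposite strand.

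Markers of other cell types were measured beside these groups. Of 8 erythroid and platelet markers, 3 rose, 0 fell and 5 did not pass, and 5 rose and 1 fell adjusted over the list alone. Hbb-bs rose from 7.10 ± 1.93 to 28.1 ± 1.51 CPM and Hba-a1 from 7.08 ± 1.27 to 25.1 ± 6.20 CPM, with counts that near-identical copies can share. Erythroid and platelet markers passed camera (adjusted p = 2.2e-04, median 1.88) but not with an estimated correlation (adjusted p = 0.305 with an estimated correlation). Of 10 B cell markers, only Ighm rose, from 114 to 153 CPM, by 0.42 ± 0.05 (edgeR adjusted p = 0.00842), and 9 did not pass. The median of the 10 was 0.27, and 7 were above 0. Cd22, Cd74 and H2-Aa had log2 fold changes of 1.59, 0.69 and 0.33 (edgeR adjusted p = 0.483, 0.188 and 0.422). Cd79a was at 0.743 and 0.73 CPM. The counts did not differ when adjusted over the list alone (camera adjusted p = 0.145, but 0.0463 without WT replicate 1). In edgeR, 0 of 10 myeloid and dendritic cell markers passed over all genes and 1 fell adjusted over the list alone. There was 1 lower at an unadjusted p under 0.05, 1 lower in DESeq2 and 0 in limma-voom, and the median was -0.09 (camera adjusted p = 0.663). Of 6 NK and cytotoxic markers, Prf1 fell by 0.56 ± 0.10 (edgeR adjusted p = 0.0282) and 5 did not pass, with the same counts adjusted over the list alone. The median of 0.26 and camera pointed up (camera adjusted p = 0.695). Prf1 was lost without any 1 of the 6 libraries (edgeR adjusted p of up to 0.101). Of 5 gamma delta T cell markers, 0 passed in edgeR by either adjustment, 0 were under an unadjusted p of 0.05, and 0 passed in DESeq2 or limma-voom (median 1.04, camera adjusted p = 0.469). The lists with fewer than 3 tested members were not tested as sets. The CD8 markers Cd8a and Cd8b1 had log2 fold changes of 0.40 and -0.10 (edgeR adjusted p = 0.692 and 0.721), and Pecam1, the 1 tested stromal and endothelial marker, had -0.08 (0.28). Xist, the transcript of the inactive X chromosome, was at 337 and 354 CPM in WT and CKO. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had a count of 0 in all 6 samples. Uty, also Y-linked, had a count of 2 in CKO replicate 1 and 0 in the other samples.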

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

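The tests on counts divided by 4, thinned libraries and corrected GC content and length were chosen after the result was seen. Ppp2ca kept its direction and passed in all 19 other settings. None of the 809 genes called in the comparison changed sign in any setting that gave them a value. The count of changed genes was 2671 with DESeq2 and 409 after correction for GC content and length, where the cause is weighed under the other observations. DESeq2 made 40 false calls of 135 on simulated data in which few genes changed, a share that need not hold here. The count of changed genes ranged from 149 to 362 when 1 library was left out, which leaves fewer samples. The count at 2-fold or more was 31 with a filter of 5 CPM, 123 with DESeq2 and 23 on log2(FPKM + 1), and it ranged from 31 to 42 with 1 library left out. The filter tests fewer genes. For DESeq2 and log2(FPKM + 1) the cause was not tested. The remaining settings without a block gave 611 to 1096 changed genes. Among the named genes and lists, the correction ended 33 calls, added 2 and left 180 on their side of the threshold, and leaving out 1 library ended from 43 to 77. The replicate block, an alternative chosen in advance, ended 105 calls and left 110 results on their side of the threshold. In both settings the results left on their side include some that had not passed before, so not all are calls that held. The 11 lists that passed camera also passed with the block, so the 105 were calls of single genes. Over all tested genes, 22 of the 809 calls remained with it. DESeq2 gave no adjusted p for 10797 genes, which were left out. Of the 11 lists that passed camera, 1 passed with an estimated correlation. That setting was stricter even for genes simulated independently. There the raised interferon list went from a camera adjusted p of 8.3e-36 with the preset correlation to 0.0251. Not passing it therefore does not by itself show that the members of a list were correlated. The estimate was 0.40 for mitochondrially encoded genes, 0.26 for erythroid and platelet markers and 0.24 for glycolysis genes. It was 0.16 for immediate early genes and 0.125 for genes that oppose Tfh. For these lists camera used a preset correlation, 0.01, below the estimate. The estimate was 0.06 for NF-kB, 0.05 for Th2, 0.04 for heat shock and 0.02 for cell cycle genes. It was below 0 for the interferon and Th17 lists. In fry, 2 of the 11 lists did not pass, and 2 other lists passed.

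Deviations of samples with the same replicate number correlated at 0.0114, -0.0052 and -0.0265. Those of samples with different numbers correlated at -0.0304 to 0.0363. No sign of pairing by number was therefore seen, though these few values cannot exclude it. With the replicate block, 22 genes passed and 11 of them changed at least 2-fold.

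With 3 samples against 3, 8 of 100 simulated 1.5-fold changes were recovered. That simulation gave 55 edgeR calls, where the data gave 809. Its limit for passing was therefore stricter, and this recovery need not hold for the data. Thinning to the smallest library gave 800 changed genes against 809.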

Other observations

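The enrichment tests, the window on chromosome 17 and the tests of a segment around Ppp2ca and of near-identical copies were chosen after the result was seen, as were the corrections for GC content, length and depth. The random sets for pairs within 2 Mb were redefined after the first result, to leave out pairs from the same list. Genes of antigen presentation were enriched among the genes higher in CKO, with 9 of 62 genes of the KEGG term (4.75-fold, hypergeometric test, adjusted p = 0.0175). Of the 9, Tap1, Hspa1a, Hspa1b, H2-T22, H2-T23 and H2-T24 lie on chromosome 17 between 34 and 37 Mb. In this window, which was drawn around them, 10 of 127 tested genes rose and 0 fell, so a pathway cannot be separated from a cluster of neighbouring genes. Of the 9, Hsp90ab1, Hspa1a, Hspa1b and Hspa5 are also in the heat shock list. The term also held the nonclassical class I genes H2-T22, from 217 to 288 CPM with a log2 fold change of 0.41 ± 0.04 (edgeR adjusted p = 0.00648), and H2-T23, with 0.39 ± 0.04 (0.00634), and counts of this family can be shared between near-identical copies. The peptide transporter gene Tap1 rose by 0.44 ± 0.07 (edgeR adjusted p = 0.0177), a call that was lost without any library but CKO replicate 3 (up to 0.0767). Genes of defense against virus were enriched 9.75-fold, with 17 of 83 genes (adjusted p = 3.8e-09), and this term shares members with the interferon list. Vegfa, the vascular growth factor gene, rose from 5.37 to 12.0 CPM, by 1.16 ± 0.11 (edgeR adjusted p = 0.00531). The term for inactivation of MAP kinases held 4 genes that rose of 11, Dusp2, Dusp4, Dusp5 and Dusp6 (adjusted p = 0.0129). Dusp4 was lost without WT replicate 2, WT replicate 3, CKO replicate 1 or CKO replicate 2 (edgeR adjusted p of up to 0.0595). Dusp5 was lost without any library but WT replicate 1 (up to 0.117) and after correction for GC content and length (0.1735).

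For the count of 809 changed genes, the 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 809 genes, and the highest of the other splits gave 8. Every other split mixes WT and CKO samples within each group of 3, so a difference between them adds to the spread and lowers the count. The counts of the other splits therefore do not show what samples without any difference would give.

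The rise of the interferon stimulated genes was set against 3 technical explanations. Myeloid or dendritic cells in the CKO samples would bring their own markers. The median of the list lay 0.6345 above that of the 10 measured markers, and the most abundant marker in CKO was at 2.63 CPM. A permutation over genes gave p = 9.2e-04 (2-sided, 100000 resamples). This p treats genes as independent and does not measure the spread between samples. A further 10 listed markers were not tested. A GC or length trend did not remove it, since the median was 0.5542 after the correction and 0.54 before, with 15 genes higher and 1 lower. One library alone was not the source, as all 3 CKO libraries lay above every WT library, at a mean log2 CPM of 4.82 to 4.86 against 4.25 to 4.29. A stronger interferon response of the CKO cells or of the animals they came from stays open as a hypothesis, and the design did not test which.

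The excess of lower over higher genes may come in part from sequence properties. After the correction for GC content and length, 37.03% of the genes called lower still passed (187 of 505), while their median log2 fold change went from -0.31 to -0.24 with a median SE of 0.05 before and after. Why calls ended was counted after this was seen. Of the 318 lower calls that ended, 248 had a smaller change and an unadjusted p above 0.0025, the highest that passed before the correction. The other 70 stayed below that limit and ended because the limit for passing fell to 0.00127. Of the 118 higher calls that ended, 62 and 56 did so in these 2 ways. The trend separates the groups, with a Spearman correlation to GC content across genes below 0 in each WT library (-0.15 to -0.28) and above 0 in each CKO library (0.17 to 0.26), so it is confounded with genotype, and a real shift of GC-poor transcripts would be removed too. A difference in depth was not the source, since 96.63% of the lower calls passed after thinning every library to the smallest total.

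Genes changed at least 2-fold, such as Slc15a2 and Ctdsp2, lay on 18 chromosomes. A segment of another strain around Ppp2ca could not account for them together, as 2.08% lay within 20 Mb of it. Of pairs from other families and lists within 2 Mb, 0 were found, where random sets gave a median of 3 and none in 4.4% of sets. The prediction that no such pair would exclude segments was wrong, because the 4 pairs of the same family or list were left out by construction. They include Hspa1a and Hspa1b in the window on chromosome 17, and a segment that changes 1 gene makes no pair. Segments from another strain therefore stay open. Reads shared between near-identical copies also stay open, since 37.5% were pseudogenes or numbered models against 27.3% of other genes of like level (Fisher's exact test, p = 0.142), and this cannot be told apart from a change in the copies.

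Within 5 Mb of Ppp2ca, 7 of 97 other tested genes were called, or 7.22% against 5.03% of all genes. Of these 7, Ccdc69 rose by 0.63 on the log2 scale and the others fell, as Ppp2ca did.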
